A study of Homo sapiens with 12 samples.

How the data were processed

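RNA sequencing libraries of MCF-7 and MDA-MB-231 cells, grown alone or with cord blood CD34+ cells for 72 h, made up 4 groups of 3 libraries, 12 in all. The authors deposited expected counts per gene, 1 table per library, made with STAR and RSEM on genome build GRCh38, per the submitters' processing notes. The versions of these tools, the annotation release and the strandedness of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited expected counts need not be whole: between 85.9% and 87.0% of the values in a library were, and all were rounded to whole numbers here.

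The tables held 60671 gene identifiers, of which 58453 were matched to GENCODE 29 for symbol, chromosome, start and end in GRCh38. The other 2218 carried at most 0.0572% of the counts of a library and were left out. A further 510 genes were left out for donor privacy, which left 57943. Total expected counts ran from 25863009 to 36823889 per library. With edgeR's filterByExpr (minimum count 10), 18610 genes were tested.

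Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersion estimates and the quasi-likelihood test in 1 fit of all 12 libraries with a mean per group and 8 residual degrees of freedom. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were co-culture against alone in each line, the difference of these changes between the lines, and the lines grown alone. Exact permutation of 3 libraries against 3 cannot give a p below 0.1, so single values were not tested that way. Gene lists with at least 5 measured members, 22 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. The lists covered mitosis, DNA replication, epithelial and mesenchymal genes, migration, YAP and TEAD targets, oestrogen response, type I interferon, antigen presentation, NF-kB, hypoxia, stress response, sterol synthesis, p53 targets, mitochondrially encoded genes, identity markers of both lines, and markers of stem and progenitor cells, leukocytes, myeloid, endothelial, fibroblast, erythroid, megakaryocyte and mast, and lymphoid cells. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined.

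The rule named protein-coding genes past the threshold with a mean of at least 1 CPM and every co-culture library beyond every library grown alone, up to the 12 largest rises and 12 largest falls. Where fewer than 10 passed, the 10 with the smallest p were given as values. Up to 4 members of each list with the smallest p could be named as examples. For the difference between the lines the genes of smallest p that passed were named, and for the lines alone the identity markers and the largest differences. IL7R, and the genes completing the count of 5 in MDA-MB-231, fall outside the rule and were chosen after their values were seen. SH3TC2 fell under the rule, among the 10 genes with the smallest p in MDA-MB-231.

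Libraries of all groups share 3 codes in their titles, taken as replicate numbers 1, 2 and 3, with no statement of what the codes stand for. Deviations from the group means correlated with r between 0.456 and 0.758 for libraries of the same line and number, between 0.136 and 0.289 for other lines with the same number, and between -0.605 and 0.12 for the same line with other numbers. Within a line, all 12 libraries matched their own number best in the other group. Across lines this did not always hold. The MCF-7 alone library of replicate 2 had r = 0.136 with the MDA-MB-231 alone library of replicate 2 and 0.152 with that of replicate 3. By the rule that every pair of the same number exceed 0.1 the numbers pair the libraries, on evidence from the data alone. Some pairs of other numbers exceeded 0.1 as well, so the rule alone does not separate them. A fit with the number as a replicate block, planned beforehand, gave 0 genes in MCF-7, and a fit with a replicate block within each line, added after these correlations were seen, gave 151. The biological coefficient of variation was 31.0% without a block and 8.79% with the block within each line.

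Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts (35008 genes), a stricter filter of 1 CPM in 3 libraries and 5 CPM in 1 (13239 genes), counts that were not rounded, only the libraries of a line, the replicate block, and leaving out each library. Leaving out all 4 libraries of replicate 1 was added later. Fold changes against a group at 0 counts were bounded with a floor of 3 counts over the group, and ratios with 1 to 3 counts carry 95% exact counting intervals. Blood-only markers were list genes detected in at least 1 library and at or under 0.1 CPM in every library grown alone.

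The tests were tried on simulated counts, with known changes in genes with a mean of at least 1 CPM. The counts were drawn from the library sizes and from the means and dispersions of the fit with the replicate block within each line. The pairing was thus built into them, so the recovery below cannot be used to choose between the fits. Without a block, 1.49% of 1.5-fold changes, 22.4% of 2-fold changes and 71.2% of 4-fold changes were recovered for MCF-7, with 0 of 63 calls on unchanged genes, among 18298 genes. For MDA-MB-231 the shares were 0%, 20.9% and 68.2%, with 0 of 59 calls on unchanged genes, among 18303 genes. With the replicate block within each line they were 70.1%, 77.6% and 95.5% for MCF-7, with 29 of 191 calls on unchanged genes, among 18309 genes. For MDA-MB-231 they were 83.6%, 83.6% and 100%, with 19 of 197, among 18306 genes, so this fit exceeded its nominal rate of false calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.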

Results

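Gene expression was measured by RNA sequencing in 2 established breast cancer cell lines, each grown alone or after 72 h in co-culture with CD34+ cells from cord blood. MCF-7 is a luminal line that carries the oestrogen receptor, and MDA-MB-231 is a triple-negative line with mesenchymal features. CD34 marks haematopoietic stem and progenitor cells, and the RNA was taken from the cancer cells. The 4 groups held 3 libraries each, 12 in all. Total expected counts ran from 25863009 to 36823889 per library. The series asks how contact with the blood cells bears on the growth and migration of the cancer cells. Values below are normalised counts scaled to library size (CPM) as mean ± SD with n = 3, and log2 fold changes are co-culture over alone unless another direction is named. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The mean chi-square per gene between libraries of a group was 94.9 to 124 for pairs with replicate 1. It was 39.3 to 49.8 between replicates 2 and 3. These values lie far above counting noise. They argue against repeat sequencing of a single library, while other technical causes stay open. Intervals cover counting error only.

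The lines grown alone differed in most of the genes measured, and the markers of both identities lay on the side known for each line. MCF-7 held the oestrogen receptor gene ESR1 at 126 ± 34.8 CPM, 422-fold above MDA-MB-231, along with the luminal transcription factors GATA3 (84.4-fold) and FOXA1 (111-fold), the luminal keratin KRT19 (3032-fold) and the progesterone receptor gene PGR (19.4-fold). MDA-MB-231 held the intermediate filament gene VIM at 4761 ± 1517 CPM, 2629-fold above MCF-7, along with the receptor tyrosine kinase AXL (5538-fold), the urokinase gene PLAU (2985-fold), the caveolin gene CAV1 (408-fold), the repressor ZEB1 (361-fold) and the hyaluronan receptor CD44 (1219 ± 152 against 40.9 ± 13.4 CPM). All 7 luminal and all 7 mesenchymal or basal-like identity markers passed the test in these directions. With edgeR's quasi-likelihood test, 10762 of 18610 genes passed an adjusted p of 0.05, 5528 of them higher in MDA-MB-231 and 5234 higher in MCF-7, and 7874 of the changes were larger than 1 on the log2 scale.

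The genes that differed most between the lines were at or near 0 counts in either MCF-7 or MDA-MB-231. CBS, the first enzyme of transsulfuration (chromosome 21, 43053191 to 43076943 in GRCh38), TSPYL5 (chromosome 8, 97273474 to 97277964) and the epithelial transcription factor GRHL2 (chromosome 8, 101492432 to 101669726) had 0 counts in all 3 MDA-MB-231 libraries. Against a floor of 3 counts over that group they were at least 7185-fold, 6951-fold and 4588-fold higher in MCF-7. The E-cadherin gene CDH1 had 1 count in MDA-MB-231 and 609 ± 18.0 CPM in MCF-7, and TFF1, an oestrogen-induced secreted peptide, had 3 counts and 1077 ± 409 CPM. Their ratios were 50950 (95% counting interval 9144 to 2012000) and 30480 (10430 to 147800). In the other direction SIGMAR1, a receptor of the endoplasmic reticulum, had 0 counts in MCF-7 and was at least 3023-fold higher in MDA-MB-231. The membrane-cytoskeleton linker MSN, the lactate dehydrogenase subunit LDHB and the transcription factor ETS1 each had 1 count in MCF-7 alone, against 2307 ± 520, 807 ± 46.5 and 442 ± 166 CPM in MDA-MB-231. Among the gene lists, 16 of 18 epithelial junction and keratin genes were lower in MDA-MB-231 by their own tests and 1 was higher, as were 19 and 1 of 22 oestrogen response genes, and 13 of 15 YAP and TEAD targets were higher. By limma's camera these lists gave adjusted p values of 5.07e-31, 4.87e-15 and 5.86e-06, and 0.000101, 0.0236 and 0.0601 as adjusted p with an estimated correlation.

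In MCF-7, co-culture with CD34+ cells went with higher levels of interferon response genes and of the genes that present antigen to T cells, as lists that did not pass with an estimated correlation (adjusted p = 0.316 and 0.270). All 28 measured members of the type I interferon list had a positive fold change, with a median log2 fold change of 0.66, and 25 of 27 antigen presentation members did, with a median of 0.52. Among them were IRF7 (ENSG00000185507, chromosome 11, 612553 to 615999), a transcription factor that amplifies interferon production, from 44.1 ± 8.72 to 78.9 ± 31.6 CPM, STAT1, the signal transducer of interferon receptors, from 493 ± 204 to 789 ± 226 CPM, and B2M (ENSG00000166710, chromosome 15, 44711487 to 44718877), the light chain of HLA class I, from 691 ± 136 to 1049 ± 200 CPM. Targets of NF-kB, a regulator of inflammation, had a median of 0.45 with 26 of 27 members positive, or 0.37 with genes of 3 counts or fewer set at their bounds or left out. Of the 27 members, 8 had 0 to 3 counts in a group, and the 5 left out had no more than 3 in either group. The signs of these members are uncertain. Oestrogen response genes lay lower, with a median of -0.20 and 18 of 22 members negative, as did DNA replication genes with -0.19 and 19 of 21 members negative. The NF-kB, oestrogen and replication lists did not pass with an estimated correlation either (adjusted p = 0.270, 0.276 and 0.615).

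By limma's camera with a preset correlation of 0.01, over 22 lists, the interferon, antigen presentation and NF-kB lists rose with adjusted p of 1.91e-13, 2.46e-14 and 1.51e-06, and with an estimated correlation they did not pass (0.316, 0.270 and 0.270). The replication and oestrogen lists fell with adjusted p of 0.000161 each, the sterol synthesis list fell with a median of -0.17 and adjusted p of 0.00117, and the mitosis list fell with a median of -0.09 and adjusted p of 0.0171. None of these falls passed once the correlation was estimated, with adjusted p of 0.615 for replication and for sterol, 0.276 for oestrogen and 0.743 for mitosis. Single libraries carried some of the falls. Without the MCF-7 alone library of replicate 2 the oestrogen list went to -0.06 (adjusted p = 0.848) and mitosis to 0.01 (0.977), and without that of replicate 1 replication went to -0.07 (0.0785) and sterol to 0.04 (0.884). Mitosis also missed the threshold without the alone library of replicate 3 (adjusted p = 0.102) and without the co-culture libraries of replicates 1 (0.910) and 3 (0.0726), and sterol without those of replicates 2 (0.0789) and 3 (0.0698). The interferon, antigen presentation and NF-kB lists passed without any single library, with adjusted p of at most 0.000335, 3.54e-05 and 0.0341, but their medians ran from 0.42 to 0.91, 0.32 to 0.71 and 0.24 to 0.79. Without the alone library of replicate 1 they were 0.42, 0.32 and 0.28. The antigen presentation median was 0.34 without the co-culture library of replicate 2, and that of NF-kB was 0.24 and 0.79 without the alone libraries of replicates 2 and 3. Seen in pairs, the interferon median was 0.77, 0.96 and 0.32 in replicates 1, 2 and 3, with 28, 28 and 27 of 28 members higher in the co-culture, and the oestrogen median was -0.05, -0.48 and -0.04. The antigen presentation median was 0.54, 0.72 and 0.26 with 24, 24 and 20 of 27 members higher, and that of NF-kB 0.51, 0.69 and 0.06 with 24, 25 and 15 of 27.

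**Figure D1:**
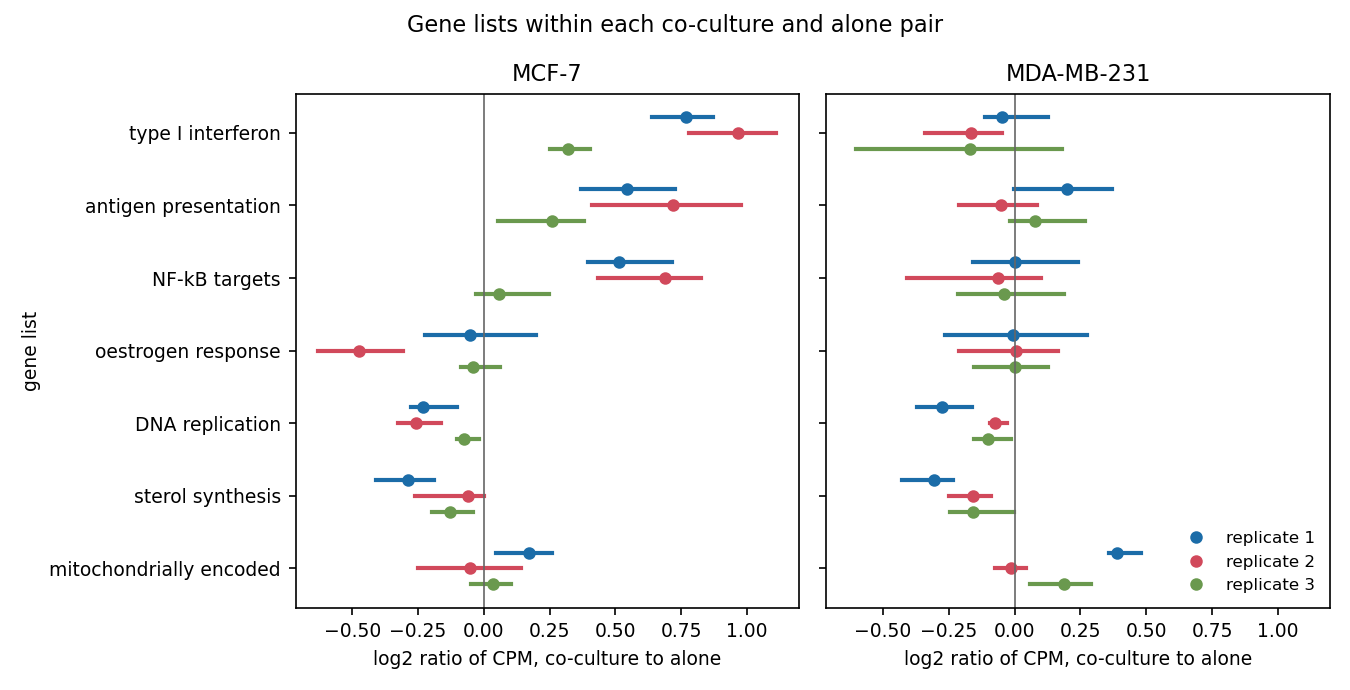
Log2 ratio of CPM of co-culture to alone (horizontal axis) for 7 gene lists (vertical axis) in MCF-7 and MDA-MB-231, with a point at the median for each replicate number and a line from the lower to the upper quartile of the members. The interferon medians of MCF-7 lie at 0.77, 0.96 and 0.32, and those of MDA-MB-231 at -0.05, -0.17 and -0.17.

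No single gene passed an adjusted p of 0.05 in MCF-7 with edgeR's quasi-likelihood test when the libraries of a group were treated as unpaired. At an unadjusted p under 0.05 there were 199 genes, and DESeq2 gave 0 genes as well. The 10 genes with the smallest p are therefore given as values. NIBAN1, a stress-responsive regulator of translation (ENSG00000135842, chromosome 1, 184790724 to 184974550), stood at 0.759 ± 0.340 CPM alone and 1.86 ± 0.264 CPM in co-culture. The phospholipid scramblase PLSCR1, an interferon-induced gene (ENSG00000188313, chromosome 3, 146515180 to 146544864), stood at 109 ± 12.9 and 176 ± 36.0 CPM. TGFBI, a secreted matrix protein induced by TGF-beta (ENSG00000120708, chromosome 5, 136028895 to 136063818), stood at 1.71 ± 0.675 and 3.74 ± 0.908 CPM. Their log2 fold changes were 1.30 ± 0.27, 0.69 ± 0.16 and 1.13 ± 0.26 (SE), each with an adjusted p of 1. NCOA7 (0.60), OTUD1 (0.65) and RFTN1 (0.62) had positive log2 fold changes, and LRP4 (-0.82), TGFBR3 (-0.76), RAMP1 (-1.05) and SPANXA2 (-2.52) negative ones. SPANXA2 belongs to a family of near-identical copies, so its reads cannot be assigned with certainty.

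Libraries with the same replicate number varied together within a line, and a fit that paired them within each line was added after the data had been seen. In that fit 151 genes passed in MCF-7, 127 up and 24 down, while the fit planned beforehand, with a replicate block shared by both lines, gave 0. Of the 127 genes that rose, 18 were among the 28 interferon genes and 8 among the antigen presentation genes. Adjusted over the list alone, 26 interferon genes and 18 antigen presentation genes rose and 1 antigen presentation gene fell. The NF-kB list held 2 genes that rose over all genes and 13 adjusted over the list alone. For the interferon and antigen presentation lists the adjusted p with an estimated correlation was 0.174 each in this fit. The fit admits false calls: on simulated counts for this comparison, 29 of its 191 calls fell on unchanged genes. The count of 151 went to 14 without both MCF-7 libraries of replicate 1, to 48 without those of replicate 2, to 299 without those of replicate 3, to 37 without both MDA-MB-231 libraries of replicate 3, and to 3 with the MCF-7 libraries fitted by themselves. DESeq2 in the same paired design gave 290 genes, and edgeR without the filter on low counts gave 718.

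In the paired fit the genes that rose most, among those with at least 1 CPM and every co-culture library above every library grown alone, were TGFBI (log2 fold change 1.14), CTSO (1.10), H2BC4 (0.85), CCN3 (0.84), IRF7 (0.79), PLSCR1 (0.68), PARP8 (0.67), SH3BGRL (0.65), APOL1 (0.60), MVP (0.57), IRF9 (0.56) and NR2F2 (0.55). CCN3, a secreted matricellular protein (ENSG00000136999, chromosome 8, 119416306 to 119424353), went from 5.08 ± 1.16 to 8.98 ± 1.38 CPM. IRF9, the DNA-binding subunit of the interferon-stimulated factor ISGF3 (ENSG00000213928, chromosome 14, 24161053 to 24166565), went from 96.4 ± 22.3 to 140 ± 17.5 CPM, and the apolipoprotein gene APOL1 went from 40.2 ± 8.86 to 60.5 ± 12.7 CPM. Adjusted p values by edgeR were 0.00907 for TGFBI, 0.00829 for CCN3 and IRF7, 0.00303 for PLSCR1, and 0.0147 for IRF9. The genes that fell by the same rule were SPANXA2 (-2.51), the agrin receptor LRP4 (-0.83), the zinc finger gene HIVEP3 (-0.73) and the cytoskeletal septin SEPTIN11 (-0.34). With the MCF-7 libraries fitted by themselves, 15 of these 16 genes did not pass, all but SPANXA2, with adjusted p from 0.0697 to 0.165. Without both MCF-7 libraries of replicates 1, 2 and 3, 13, 11 and 4 of the 16 lost the call, and without both MDA-MB-231 libraries of replicates 1, 2 and 3, 5, 4 and 12 did, with adjusted p up to 0.482. PLSCR1 and SPANXA2 passed in all 6 of these fits. IRF9 missed the threshold without the MCF-7 pairs of replicates 1 (adjusted p = 0.114) and 2 (0.109) and the MDA-MB-231 pair of replicate 3 (0.0800). With DESeq2 in the same paired design CTSO (adjusted p = 0.136) and H2BC4 (0.114) did not pass, nor did CTSO with RLE size factors (0.0514). The interferon genes XAF1 (0.79) and CMPK2 (0.93) and the HLA class I genes HLA-A (0.74), HLA-C (0.65) and HLA-E (0.51) also rose, as did the chemokine gene CXCL8 (0.99 in the unpaired fit, where it was -0.16 without the co-culture library of replicate 1). The sterol enzyme FDFT1 fell by 0.47, the single sterol gene that passed over all genes, and 9 sterol genes fell when adjusted over the list alone. The replication helicase genes MCM2 (-0.37) and MCM5 (-0.30) had an adjusted p of 0.0513, and 9 replication genes fell and 1 rose adjusted over the list alone. Among oestrogen response genes 0 passed over all genes and 5 fell adjusted over the list alone, with log2 fold changes of -0.99 for PDZK1, -0.30 for the cyclin gene CCND1 and -0.28 for ESR1.

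**Figure D2:**
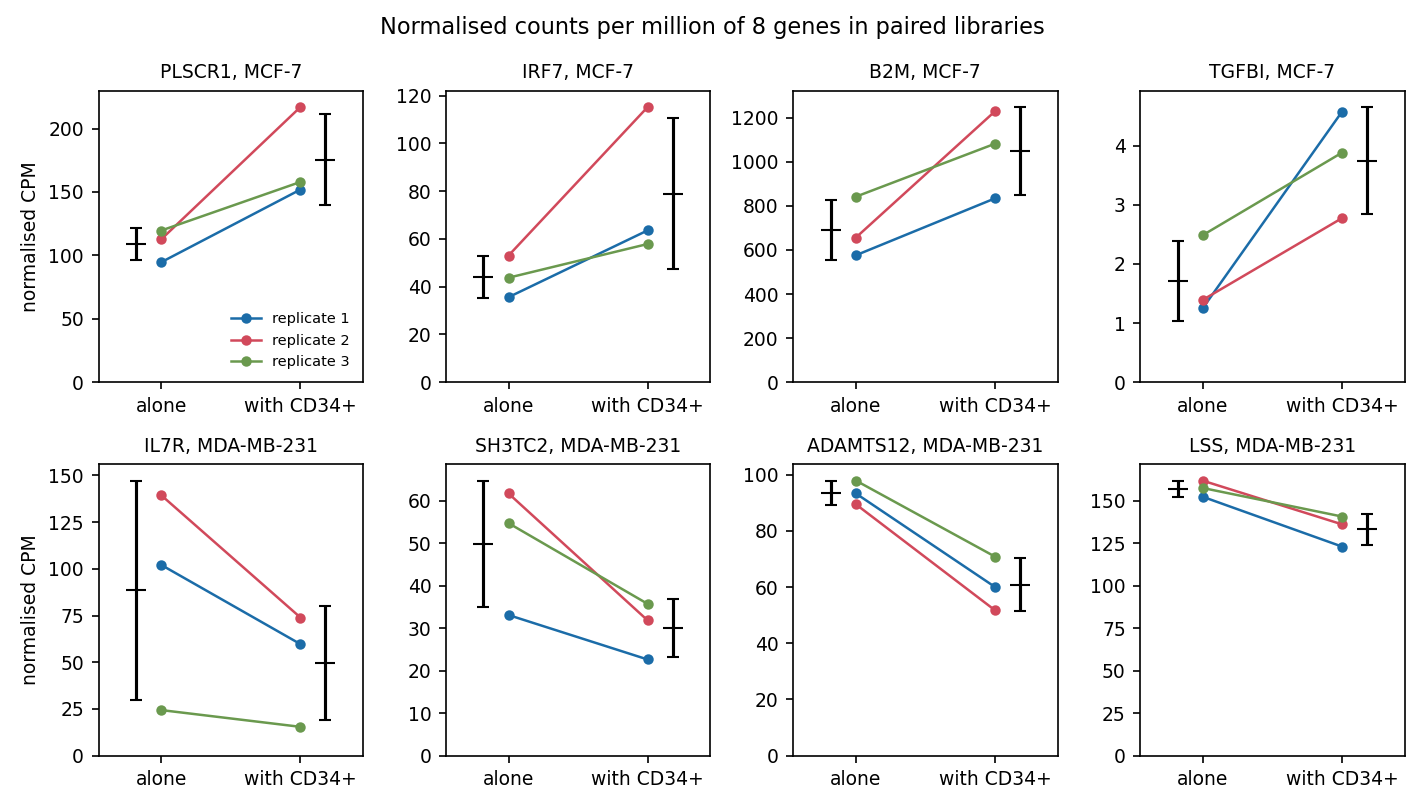
Normalised CPM (vertical axes) of 8 genes in cultures alone and with CD34+ cells (horizontal axes), with a point per library, lines joining libraries of the same replicate number, and the group mean ± SD in black (n = 3). B2M went from a mean of 691 to 1049 CPM in MCF-7 and ADAMTS12 from 93.6 to 60.9 CPM in MDA-MB-231.

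Of the lists closest to the question of growth and migration, those other than replication and mitosis did not pass in MCF-7. Invasion proteases and integrins had a median log2 fold change of 0.13 (adjusted p = 0.304), epithelial genes 0.05 (0.775), mesenchymal genes 0.04 (0.117) and YAP and TEAD targets -0.03 (0.921). Medians and adjusted p values were -0.00 and 0.775 for hypoxia and glycolysis, 0.02 and 0.304 for the stress response, 0.06 and 0.304 for p53 targets, 0.07 and 0.480 for mitochondrially encoded genes, and -0.03 and 0.265 for the luminal identity genes. The YAP list had a negative median but a positive mean of 0.09. In the paired fit the p53 list rose with a median of 0.11 and adjusted p of 0.0281 (0.415 as adjusted p with an estimated correlation). It did not pass without both MCF-7 libraries of replicate 2 (median 0.04, adjusted p = 0.296), with no filter on low counts (0.0687) or with the MCF-7 libraries fitted by themselves (0.0527). Of the mesenchymal list, TGFBI passed adjusted over the list alone in the unpaired fit, as AXL did on the MDA-MB-231 identity list, with 12 counts alone and 36 in co-culture. On the other lists 0 genes passed adjusted over the list alone in that fit. ZEB2 had 0 counts alone and 10 in co-culture, and TCF4 had 0 and 4.

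Blood cell transcripts were highest in the co-culture libraries of replicate 1. The 32 blood cell markers that were detected in at least 1 library and stayed at or under 0.1 CPM in every library grown alone summed to 3.91 CPM (95% counting interval 3.22 to 4.70) in the MCF-7 co-culture of replicate 1 and 5.55 CPM (4.77 to 6.43) in that of MDA-MB-231, against 0.193 to 0.895 CPM in the other 10 libraries. The co-cultures of replicate 3 also stood above their partners grown alone. Counts were 24 against 9 in MCF-7 (0.895 CPM, 0.573 to 1.33, against 0.337, 0.154 to 0.639), where the intervals overlap. They were 26 against 5 in MDA-MB-231 (0.804 CPM, 0.525 to 1.18, against 0.193, 0.0628 to 0.451). In replicate 2 the counts were 14 against 13 in MCF-7 and 17 against 7 in MDA-MB-231. The markers were chosen for low levels in the libraries grown alone, with no such limit on the co-cultures. That choice favours the co-cultures, and the intervals do not allow for it. MPO, the peroxidase of myeloid granules, had 58 and 56 counts in the co-cultures of replicate 1, and the pan-leukocyte phosphatase PTPRC had 13 and 19. The pan-leukocyte list rose in MCF-7 with a median of 0.49 (adjusted p = 0.0168, or 0.276 as adjusted p with an estimated correlation), and with genes of 3 counts or fewer set at their bounds or left out the median was 0.27. The MDA-MB-231 identity list rose with 0.37 (adjusted p = 0.0119, or 0.613 with an estimated correlation). Without the MCF-7 co-culture library of replicate 1 these medians went to -0.01 and -0.72, and without all 4 libraries of replicate 1 to 0.02 and 0.22. Without the alone libraries of replicates 2 and 3 the adjusted p was 0.109 and 0.139 for the pan-leukocyte list and 0.229 and 0.247 for the identity list. Neither list passed with the replicate block (adjusted p = 0.0816 and 0.105). The MCF-7 co-culture library of replicate 1 held 31 counts of MSN, 24 of the granule proteoglycan gene SRGN and 167 of VIM, against at most 2, 3 and 75 in the other MCF-7 libraries, and MSN and SRGN passed in the paired fit with adjusted p of 0.00378 and 0.0263. MDA-MB-231 alone holds MSN and VIM at high levels, as given above, and SRGN at 115 to 141 CPM. Blood cells and cross-talk from MDA-MB-231 therefore cannot be told apart as the source of these counts. The other markers did not pass in MCF-7: stem and progenitor cells had a median of -0.08 (adjusted p = 0.775), myeloid cells 0.05 (0.304), endothelial cells -0.08 (0.828) and fibroblasts 0.06 (0.830), the last with a mean of -0.23. Erythroid, megakaryocyte and mast cell, and lymphocyte lists had 2 measured members each and were not tested.

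**Figure D3:**
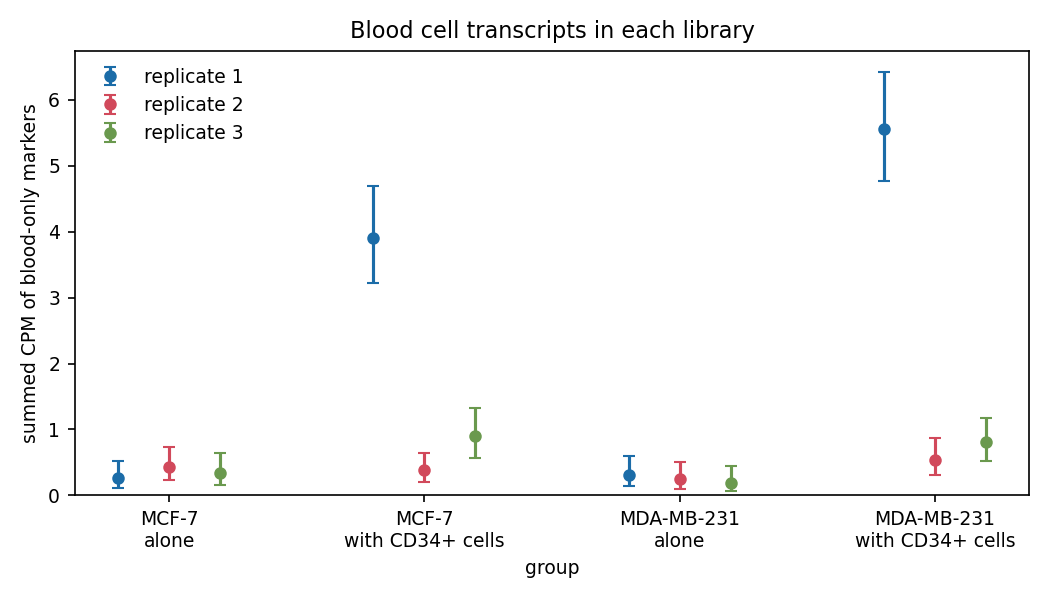
Summed CPM (vertical axis) of 32 blood cell markers, detected in at least 1 library and at or under 0.1 CPM in every library grown alone, in each of the 12 libraries, with 95% counting intervals. The co-culture libraries of replicate 1 stand at 3.91 CPM in MCF-7 and 5.55 CPM in MDA-MB-231, and the other 10 libraries lie between 0.193 and 0.895 CPM.

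In MDA-MB-231, co-culture went with slightly lower levels of genes for cholesterol and fatty acid synthesis and for DNA replication, and slightly higher levels of mitochondrially encoded messenger RNAs. None of these 3 lists passed with an estimated correlation (adjusted p = 0.885, 0.963 and 0.885), and without the alone library of replicate 1 replication passed as a rise and the mitochondrial median was -0.01. The sterol list had a median log2 fold change of -0.19 with 20 of 21 members negative. Examples were LSS, which closes the sterol rings, from 157 ± 4.73 to 133 ± 9.20 CPM, CYP51A1, the sterol demethylase, from 236 ± 44.5 to 184 ± 28.7 CPM, and PCSK9, which lowers the LDL receptor, from 63.4 ± 18.5 to 47.2 ± 23.9 CPM. The replication list had a median of -0.17 with 19 of 21 members negative, among them the folate enzyme gene DHFR (-0.33) and the reductase subunit RRM1 (-0.17). The mitochondrial list had a median of 0.18 with 11 of 13 members positive, among them MT-ND1 (0.32) and MT-ND2 (0.22), subunits of respiratory complex I.

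By camera with the preset correlation, these 3 lists of 22 passed: sterol fell (adjusted p = 0.000669), replication fell (0.00297) and the mitochondrial list rose (0.0120). The adjusted p with an estimated correlation was 0.885, 0.963 and 0.885. Without the MDA-MB-231 alone library of replicate 1 replication passed in the opposite direction, with a median of 0.18 (adjusted p = 0.0220), and the mitochondrial median was -0.01 (adjusted p = 0.945). Replication also missed the threshold without the co-culture libraries of replicates 2 (adjusted p = 0.237) and 3 (0.821), and the mitochondrial list without the alone library of replicate 3 (0.115) and the co-culture library of replicate 2 (0.468). The sterol median was 0.07 without the alone library of replicate 3 (adjusted p = 0.940, with the test still downward), -0.03 without the co-culture library of replicate 1 (adjusted p = 0.755) and -0.10 without that of replicate 2 (adjusted p = 0.174). In pairs the sterol median was -0.31, -0.16 and -0.16, that of replication -0.27, -0.08 and -0.10, and that of the mitochondrial list 0.39, -0.01 and 0.19, with 12, 6 and 10 of 13 members higher. In the paired fit 12 sterol genes fell adjusted over the list alone and 0 over all genes, and the type I interferon list fell with a median of -0.15 and adjusted p of 0.0206 (0.799 as adjusted p with an estimated correlation). That list did not pass without both MDA-MB-231 libraries of replicate 2 (median -0.08, adjusted p = 0.419) or 3 (0.121), or with no filter on low counts (0.108).

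No single gene passed in MDA-MB-231 with edgeR's quasi-likelihood test and unpaired libraries. At an unadjusted p under 0.05 there were 128 genes, and DESeq2 gave 0. The 10 genes with the smallest p were the histone gene H4C14 (log2 fold change 1.19), SH3TC2 (-0.73), KCTD13 (0.37), the histone gene H4C15 (a mean of 2.22 CPM alone and 1.11 CPM in co-culture), BBLN (0.35), RGPD5 (-2.34), the histone gene H2BC21 (-0.46), P4HTM (0.41), DCXR (0.33) and C7orf25 (-0.97). H4C14 and H4C15 are near-identical copies with opposite signs, and RGPD5 belongs to a family of near-identical genes, so these values are uncertain. The replicate block shared by both lines gave 0 genes, and the fit paired within each line gave 5, 1 up and 4 down. The metalloprotease gene ADAMTS12 (ENSG00000151388, chromosome 5, 33523535 to 33892192) fell by 0.63 on the log2 scale (adjusted p = 0.0385), from 93.6 ± 4.22 to 60.9 ± 9.57 CPM. The interleukin 7 receptor gene IL7R (ENSG00000168685, chromosome 5, 35852695 to 35879603) fell by 0.79, from 88.6 ± 58.7 to 49.7 ± 30.5 CPM, and SH3TC2 (ENSG00000169247, chromosome 5, 148923639 to 149063163) fell by 0.71, from 49.8 ± 14.9 to 30.0 ± 6.72 CPM, each with an adjusted p of 0.0184. AC002310.5 and AL591806.3, named because the count was small, completed the 5. AL591806.3 had 0 counts alone and 7, 31 and 0 in the co-cultures of replicates 1, 2 and 3, against 261 to 829 in the MCF-7 libraries. The count of 5 became 30 with DESeq2 in the same paired design, 72 with the MDA-MB-231 libraries fitted by themselves, 3 with the stricter filter (where ADAMTS12 did not pass, adjusted p = 0.0503), 2 and 1 without both MDA-MB-231 libraries of replicates 1 and 3, and 23, 32 and 13 without both MCF-7 libraries of replicates 1, 2 and 3. Without both MDA-MB-231 libraries of any replicate number ADAMTS12, IL7R and SH3TC2 did not pass, with adjusted p from 0.0742 to 0.363. On simulated counts for this comparison 19 of its 197 calls fell on unchanged genes.

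The other lists did not pass in MDA-MB-231 with unpaired libraries, with adjusted p from 0.150 to 0.994. Median log2 fold changes were -0.04 for mitosis, -0.02 for epithelial, -0.10 for mesenchymal and -0.06 for migration genes, 0.03 for YAP and TEAD targets and -0.06 for the oestrogen response. Immune lists stood at -0.14 for type I interferon, 0.09 for antigen presentation and -0.04 for NF-kB. Hypoxia and glycolysis stood at 0.08, the stress response at 0.04, p53 targets at 0.02, luminal identity at 0.17 and mesenchymal or basal-like identity at -0.03. Other cell types stood at 0.07 for stem and progenitor cells, -0.13 for leukocytes, 0.26 for myeloid cells, -0.10 for endothelial cells and -0.03 for fibroblasts. The mean had the opposite sign to the median for epithelial genes (0.17), YAP and TEAD targets (-0.02), oestrogen response (0.02) and stem and progenitor cells (-0.08). The HLA class II gene HLA-DRA had 1 count alone and 32 in co-culture, 24 of them in replicate 1.

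Whether co-culture acted differently in the lines was tested directly, as the change in MDA-MB-231 minus that in MCF-7. The interferon list differed by a fitted median of -0.75 on the log2 scale (27 of 28 members negative), the NF-kB list by -0.47, the antigen presentation list by -0.46, the pan-leukocyte list by -0.62 and the MDA-MB-231 identity list by -0.42, and the oestrogen and MCF-7 identity lists by 0.13 and 0.52. Some of these lists hold members near 0 counts, whose fitted values depend on the prior count. Some pan-leukocyte genes are abundant in MDA-MB-231 and near 0 in MCF-7, so unequal baselines alone may give the difference of that list. Adjusted p by camera was 1.53e-09, 6.65e-05, 0.000207, 0.00341, 0.0135, 0.0308 and 0.0308 in this order, and from 0.231 to 0.589 with an estimated correlation. With the replicate block shared by both lines the MDA-MB-231 identity, oestrogen and MCF-7 identity lists did not pass (adjusted p = 0.0881, 0.0664 and 0.0881), and with the block within each line the identity lists did not (0.0844 and 0.0857). With unpaired libraries 0 genes passed edgeR's test (164 at an unadjusted p under 0.05, 0 with DESeq2). The paired fit gave 25, 3 higher and 22 lower in MDA-MB-231, among them the interferon-induced gene NMI, which stood at 33.4 ± 8.56 CPM alone and 59.2 ± 25.5 CPM in co-culture in MCF-7 and at 15.6 ± 2.38 and 12.6 ± 1.72 CPM in MDA-MB-231. NMI did not pass without both MDA-MB-231 libraries of replicate 3 (adjusted p = 0.0859). That count was 2 to 129 when both libraries of a line and replicate number were left out, and 98 with DESeq2 in the same paired design.

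No gene passed in both lines, with unpaired libraries or in the paired fit, where independent lists would share 0.00682 genes up and 0.00516 down. With DESeq2, 0 genes were shared in the unpaired design and 4 in the paired design. Across the 18610 genes the log2 fold changes of the lines had a Pearson correlation of 0.05 and a Spearman correlation of 0.08, and 0.14 and 0.13 across the 10060 genes with at least 5 CPM in both lines, of which 54.6% changed in the same direction. Genes are not independent replicates, so these are descriptions only.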

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

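The tests of technical explanations were written after the results had been seen, as were the splits of the counts of genes in MCF-7, in MDA-MB-231, in both lines and in the difference between the lines. The splits of the gene lists, of the lines alone and of the fits paired within each line were written before. The tests of blood RNA and of cross-talk were changed after a result was seen, as stated beside them.

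With unpaired libraries, the log2 fold change in co-culture differed between the lines for 7 gene lists at the preset correlation and for none of them with an estimated one. The difference was the change in MDA-MB-231 minus that in MCF-7. The fitted median log2 difference was -0.75 for type I interferon, -0.46 for antigen presentation, -0.47 for NF-kB, -0.62 for leukocytes, -0.42 for the MDA-MB-231 identity markers, 0.13 for the oestrogen response and 0.52 for the MCF-7 identity markers. By camera the adjusted p ran from 1.53e-09 to 0.0308, and none passed with an estimated correlation (adjusted p from 0.231 to 0.589). In MCF-7, without the co-culture library of replicate 1, the leukocyte median went from 0.49 to -0.01 and the MDA-MB-231 identity median from 0.37 to -0.72. Of 12 leukocyte genes, 8 were higher in MDA-MB-231 alone and 4 in MCF-7 alone. LAPTM5 stood at 154 to 252 CPM in MDA-MB-231 alone and at most 0.234 CPM in MCF-7 alone. The same trace of blood RNA would move such a ratio more in MCF-7. For the leukocyte list, a differing response and unequal baselines cannot be told apart. With the replicate block planned beforehand the MDA-MB-231 identity, MCF-7 identity and oestrogen lists did not pass (adjusted p = 0.0881, 0.0881 and 0.0664), and with the block within each line neither identity list did (0.0844 and 0.0857). In the fit paired within each line, which gave 25 genes where the unpaired fit gave 0 in edgeR (164 at an unadjusted p under 0.05, and 0 in DESeq2), the named genes had log2 differences of 2.10 for SPANXA2, 2.00 for CLEC11A, -1.09 for NMI, -2.51 for AC008012.1, -0.83 for GPRC5A, -0.82 for RIGI and -0.73 for DDX60L. In the 6 fits without both libraries of a line and replicate number, CLEC11A lost the call in 5, RIGI and DDX60L in 4 each, SPANXA2 and GPRC5A in 2 each, and NMI and AC008012.1 in 1 each, with adjusted p from 0.0507 to 0.214, and CLEC11A lost it with DESeq2 as well (0.0930). The fitted values of 6.30 for AL591806.3, with 0 counts in MDA-MB-231 alone, and -4.70 for MSN, with 1 count in MCF-7 alone, depend on the prior count, and these genes lost the call in 3 and 2 of the 6 fits.

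Interferon and antigen presentation genes were higher in MCF-7 co-cultures, with 28 of 28 interferon genes positive. By camera with an estimated correlation neither list passed (adjusted p = 0.316 and 0.270 with unpaired libraries, and 0.174 each in the paired fit). With unpaired libraries 0 of their genes passed over all genes. For the interferon genes, RNA carried over from blood cells was argued against by the pair of replicate 2. Blood-only markers there summed to 0.380 CPM (upper bound 0.638) against 7.76 CPM needed if they rose with the interferon genes as in replicate 1. The argument holds only if the ratio of these markers to the interferon gain was the same in both pairs, which was not tested. That test replaced an earlier one, a ratio of blood-only markers in that pair (0.878, 95% interval 0.383 to 2.03), which had left the question open. Depth was argued against by the pair of replicate 3, whose totals differed by 0.405% and whose interferon genes had a lower quartile of 0.25 on the log2 scale. The antigen presentation genes were put to neither test. A response of the cancer cells to the CD34+ cells is a candidate explanation that the design names but these tests do not show, and an unlabelled difference between the cultures may remain.

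Blood cell transcripts in the co-culture libraries of replicate 1 summed to 3.91 CPM in MCF-7 and 5.55 CPM in MDA-MB-231. None of the other 10 libraries held more than 0.895 CPM of these markers. Cross-talk cannot lift a gene above its source, so this argued against cross-talk from the other 4 co-culture libraries. The 6 libraries grown alone were low by the choice of markers. Their sums of 0.193 to 0.433 CPM there, with 0 counts of MPO, were set by that choice and are no evidence by themselves. The choice did not set the levels in the co-cultures. Since cross-talk cannot lift a gene above its source, those levels argued against the libraries grown alone as the source of these markers only. LYZ, which was not among the chosen markers, had at most 3 counts in each of these 6 against 25 and 37, which argued against cross-talk from them for LYZ as well. A test added later on all 99 blood list genes, whatever their level, asked for at least 3 genes above each of the other 10 libraries beyond counting error, a number set after the counts of MPO and LYZ had been seen. It found 2 in MCF-7 (LYZ and MPO) and 5 in MDA-MB-231 (these with HDC, PTPRC and SPN), fewer than asked in MCF-7, so that test decided nothing by itself. The MCF-7 co-culture of replicate 2 had 3 genes above each other library outside the co-cultures of replicate 1, namely PTPN6, S100A8 and S100A9. MCF-7 grown alone already held these, at 18.9 to 26.2, 41.6 to 61.0 and 117 to 174 CPM. Carry-over of the CD34+ cells or their progeny may account for the transcripts in the co-cultures of replicate 1. The marker counts in these libraries correlated with a Spearman coefficient of 0.402 across markers (permutation p = 0.0124), and markers are not independent replicates. Any source shared by these libraries would give such a correlation, as would cross-talk between them, which was not tested. The coefficient therefore does not favour carry-over. Among the markers MPO had 58 and 56 counts and PTPRC 13 and 19.

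NIBAN1 and TGFBI stood higher in MCF-7 co-cultures, and both are abundant in MDA-MB-231. Their gains were 0.555% and 1.81% of the MDA-MB-231 levels. Cross-talk at a common share would lift other genes abundant there and near absent from MCF-7 by about as much. Over 152 such genes the median gain was 0.017% and the 95th percentile 0.413%, which argued against cross-talk at a common share. Both genes were named for small p in these libraries, so their place above that percentile is no evidence by itself. This test was first written for AXL as well, whose gain of 0.0318% did not exceed that percentile, so AXL was given a test of its own, and for it cross-talk cannot be told apart because a gain this small lies within that of the other genes. For carried-over blood RNA the pair of replicate 2 was examined, where blood-only markers were low and the smaller log2 ratio of NIBAN1 and TGFBI was 0.96. Both genes were named for small p over all MCF-7 libraries, which favours a rise in each pair. That test therefore does not decide. A response of the cancer cells stays open and was not tested further.

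Other splits of the same libraries were tried for each count. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. As many genes as in the real split (0) were found in 10 of 10 splits for MCF-7 and in 10 of 10 for MDA-MB-231, with 1 the highest of the others in each, and the lines alone gave 10762 genes in the real split against 0 at most in the others (1 of 10). For the gene lists, 6 of 10 splits gave as many as the real 9 in MCF-7, with 13 the highest of the others, and 7 of 10 as many as the real 3 in MDA-MB-231, with 7 the highest. Other splits thus gave as many lists at the preset correlation. Of 100 splits drawn, 100 gave as many genes as the real 0 for the difference between the lines (highest other 5) and 100 for both lines (highest other 0). Every split reaches a real count of 0 whatever the data, so these splits and those of the genes in each line decide nothing. With pairs kept within each line there are 4 splits per line and 16 for the difference, again too few. The real 151 genes in MCF-7 compare with 3 at most in the others (1 of 4), the real 5 in MDA-MB-231 with 2 (1 of 4), and the real 25 of the difference with 5 (1 of 16). The real 8 lists in MCF-7 compare with 9 (3 of 4) and the real 4 lists in MDA-MB-231 with 5 (4 of 4).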

How the results depend on the processing

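The replicate block within each line, its alternatives, and the fits without all 4 libraries of replicate 1 were chosen after seeing the data. Counts of calls stayed within 1.5 times under 167 alternatives, with 0 against 0 taken as kept, and moved further under 40. Of the other values, 2286 kept their direction and side of the threshold, 163 kept their direction and no longer passed, 19 newly passed and 14 reversed. The 2286 include 938 values of genes in MCF-7 and 456 in MDA-MB-231 from the unpaired fit, where no gene passed and no call could be lost. With the block within each line, values of named genes kept the call 109 times and lost it 67 times in MCF-7. They kept it 23 times and lost it 10 times in MDA-MB-231, and 64 and 25 times for the difference between the lines. Except where a setting has fewer libraries or genes, the cause was not tested. The genes differing between the lines alone numbered 8124 to 12817 under all alternatives, and 9832 to 11122 when a library was left out. Genes changed in both lines stayed at 0 in the unpaired fit. With the replicate block within each line, genes went from 0 to 151 in MCF-7, to 5 in MDA-MB-231 and to 25 for the difference between the lines, while the block shared by both lines left all 3 at 0. Counts of lists went to 0 with an estimated correlation in every case, from 9 in MCF-7 and 3 in MDA-MB-231, and from 8 and 4 with the block. Leaving out a library gave 6 to 13 lists in MCF-7 and 2 to 7 in MDA-MB-231, with 6 without the MDA-MB-231 alone library of replicate 1, 5 without that of replicate 2 and 7 without the co-culture library of replicate 3.

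With the replicate block within each line, the 151 genes in MCF-7 became 290 with DESeq2, 718 with no filter on low counts and 3 with that line alone. Without both MCF-7 libraries of replicates 1, 2 and 3 they became 14, 48 and 299, and without both MDA-MB-231 libraries of replicate 3, 37. The 5 genes in MDA-MB-231 became 30 with DESeq2, 242 with no filter, 72 with that line alone and 3 with the stricter filter, then 23, 32 and 13 without the MCF-7 pairs and 2 and 1 without the MDA-MB-231 pairs of replicates 1 and 3. The 25 of the difference became 98 with DESeq2 and 343 with no filter, 6 and 129 without the MCF-7 pairs of replicates 1 and 3, and 5, 6 and 2 without the MDA-MB-231 pairs of replicates 1, 2 and 3. The 0 genes in both lines became 4 with DESeq2, 34 with no filter and 1 with RLE size factors, then 1, 3 and 3 without the MCF-7 pairs and 1 without the MDA-MB-231 pair of replicate 1.

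Reversed values came from leaving out libraries, and ranges over all such fits follow them. In MCF-7 without the alone library of replicate 1, the log2 fold change of CD44 became 0.013 (-0.72 to 0.013) and the sterol median 0.038 (-0.42 to 0.038), and without that of replicate 2 the mitosis median became 0.014 (-0.17 to 0.014). Without the co-culture library of replicate 1, CXCL8 became -0.16 (-0.16 to 2.02), EVI2B 0 (0 to 3.75), the MDA-MB-231 identity median -0.72 (-0.72 to 1.08) and the leukocyte median -0.011 (-0.011 to 1.49), and EVI2B was 0 as well without all 4 libraries of replicate 1. In MDA-MB-231 without the alone library of replicate 1, CDC45 became 0.099 (-0.45 to 0.099), MCM6 0.092 (-0.40 to 0.092), MT-CO2 -0.011 (-0.011 to 0.41), MT-ND4 -0.057 (-0.057 to 0.62), the mitochondrial median -0.011 (-0.011 to 0.38) and the replication median 0.18 (-0.42 to 0.18), which then passed as a rise (adjusted p = 0.0220). Depth limits genes near 0 counts, and with 3 libraries per group the unpaired fit recovered few changes of 2-fold in counts simulated with the pairing built in.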

Other observations

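Inflammatory and stress genes gave further values in the co-cultures, none of which passed edgeR's test over all genes with unpaired libraries. In MDA-MB-231 the neutrophil-attracting chemokine genes CXCL2 and CXCL3 had log2 fold changes of 0.48 and 0.58, and the interferon-induced RNA sensor RIGI -0.31. In MCF-7 the p53 target TP53INP1 had a log2 fold change of 0.55, and the NF-kB genes TNFAIP3 and NFKB2 had 0.40 each. Hypoxia and glycolysis genes had median log2 ratios of 0.41, -0.32 and 0.02 in the MCF-7 pairs of replicates 1, 2 and 3 and of 0.33, 0.05 and -0.04 in those of MDA-MB-231. The stress response genes had -0.16, 0.27 and -0.01 in MCF-7 and -0.03, 0.10 and 0.10 in MDA-MB-231.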
